A study of Mus musculus with 32 samples.

How the data were processed

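RNA of thymocytes from 12 groups of mice was measured on 32 Agilent whole-genome mouse arrays, 1 array per sample. Per the labels' protocols, RNA was isolated with TRIzol and RNeasy columns, 500 ng was labelled with Cy3 by the Agilent QuickAmp kit, and the arrays were read in 1 channel. The deposited scanner files hold the intensity of each spot as Agilent Feature Extraction wrote it, version 9.5.3 per the submitters' processing notes and 9.5.3.1 per the file headers. Per the file headers, the processed intensity had its local background removed by a spatial trend surface and was not scaled between arrays. The authors also deposited tabulated values with log2 intensities of nearly equal quantiles in every column, whose method is not stated. That table served as an alternative only.

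Each array held 43379 spots beside 1639 control spots, for 41174 probes, of which 245 were on more than 1 spot and were averaged. Spots with a non-uniformity or population outlier flag, 0.223% of values, were set to missing. Values were log2 processed intensity minus the 75th percentile of the array. Probes well above background on at least 4 of the 32 arrays were kept, and the probe with the highest mean stood for its gene name. Gene names came from the files. An accession match to the reference annotation, which is of another build, gave a current symbol for 22951 probes and updated 5141, leaving 28786 names. Coordinates are those of the files (build mm7). The percentage of probes well above background shows how far down each array measured, and the number of arrays limits the precision. Where no array on one side of a comparison was well above background, a fold is given as a lower bound, against the lowest signal called well above background on each array or the gene's own value where that was higher.

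Tests were two-sided contrasts of group means in limma 3.58.1 (lmFit, eBayes) under R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Files were read with data.table (1.17.8) and jsonlite 2.0.0, and figures drawn with matplotlib 3.10.9 under Python 3.11.15. P72 and R72 comparisons used their 24 arrays with no block. The p53+/+ and p53-/- comparisons used all 32 arrays, because their irradiated groups held 1 array each. Those lone arrays were assumed to vary like the others, and 2 h and 4 h were averaged. There were 17 comparisons: each later time against each earlier one within P72 and R72, the genotypes at each time and over all times, the differences of their responses at 2 h and 4 h, and the genotype, irradiation and difference contrasts of p53+/+ and p53-/-.

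Fixed before the data were examined were 26 gene lists: p53 targets (apoptosis, cell cycle with DNA repair and feedback, metabolism and other), NF-kB targets, inflammatory caspases and inflammasome, interferon-stimulated genes, Toll-like receptors and sensing, G1/S and replication, G2/M and mitosis, immediate early genes, heat shock, unfolded protein response, glucocorticoid-responsive and circadian clock genes, markers of double positive, single positive and double negative thymocytes, of B cells, macrophages, dendritic cells, neutrophils, erythroid cells, thymic epithelium, fibroblasts with endothelium and adipocytes, and sex-linked genes. Lists were tested with camera (inter-gene correlation preset to 0.01), beside it camera with an estimated correlation and fry, adjusted over the lists of a comparison. The design, tests, alternatives and the rule for named genes were fixed at the same point. The rule always names Trp53, Cdkn1a, Mdm2, Bbc3, Pmaip1, Bax, Fas, Ccng1, Trp53inp1, Casp4, Casp1, Tnf and Nfkbia. It adds per comparison up to 8 genes that rose most and 8 that fell most, past the threshold and with values that do not overlap between the sides (past the threshold only for differences of responses), and up to 4 members with the smallest p of each list described. Names that are only identifiers are left out. The text takes the top of each part.

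Genes that rose more in p53+/+ than in p53-/- and were higher in irradiated p53+/+ formed the p53-dependent list, limited to the 100 with the smallest p. Its means on the P72 and R72 arrays were compared by exact permutation of arrays.

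The fits were tested on data simulated from the arrays' means and spread for 20479 genes, with 200 changed beside a shifted list. For P72 at 2 h against 0 h 168 genes were called, 10 falsely, and 47.8%, 67.2% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold were recovered. For P72 against R72 at 2 h these were 37.3%, 71.6% and 89.4%, for the difference of responses at 4 h 14.9%, 49.3% and 81.8%, and for irradiated p53+/+ against p53-/- 31.3%, 58.2% and 83.3%. For the difference between p53+/+ and p53-/- responses they were 2.99%, 43.3% and 72.7%.

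Alternatives fixed in advance were normexp background correction (offset 50), quantile normalization, the authors' value table, no filter and a filter on all 32 arrays, a block for the replicate number, the slide as a fixed or random block, other sets of arrays in the fit, all probes one by one, a fold of at least 1.5, and leaving out each array in turn. Added after the data were seen were centring on the median of the tested genes, a block for scan date, the first or the later scan dates alone, a block for sex, and normexp with the local background capped at 2 times the array's median. Arrays came from 8 slides and 4 scan dates, read from the file headers. Within-slide values compare arrays of one slide. To test directions within a slide, a check added after the results were seen, genes were called in a fit without the arrays of that slide. No array was left out of the main comparisons, and 0 sample columns were unused.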

Results

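RNA levels were measured in thymocytes of 6-week-old C57Bl/6 mice before and after whole-body gamma irradiation with 5 Gy, on 32 single-colour Agilent mouse arrays. P72 and R72 mice carry proline or arginine at codon 72 of p53 and were each measured at 0, 2 and 4 h with 4 arrays per group. Mice labelled p53+/+ and p53-/- were each measured on 2 untreated arrays, 1 array at 2 h and 1 array at 4 h. The series asks whether the codon 72 variants differ in the response to irradiation, with attention to genes of immunity and inflammation and to the transcription factor NF-kB. Per the labels each sample pooled 2 mice, and the 4 arrays of a P72 or R72 group were independent experiments. The labels do not say whether the 2 untreated p53+/+ arrays, or the 2 untreated p53-/- arrays, came from different pools, and they were analysed as separate samples. The 75th percentile of the signal ranged from 268 to 1031.5 fluorescence units between arrays, and 52.2% to 71.2% of probes were well above background. No spot was saturated. The correlation across genes between arrays of one group was lowest at 0.9744 (R72 at 2 h) and highest at 0.995 (untreated p53-/-). Genes are not independent replicates, so these correlations describe the arrays alone. The first 3 principal components held 52%, 6.4% and 5.83% of the variance. Levels below are log2 signal minus the 75th percentile of the array. Changes are on the log2 scale with the standard error of the limma fit after ±.

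Trp53, the targeted gene, was measured on every array by a selected probe at chromosome 11, 69662031 to 69662089 (build mm7, per the file headers). Its level was 0.25 ± 0.17 (SD, n = 12, range -0.13 to 0.46) on the P72 arrays and 0.15 ± 0.32 (SD, n = 12, range -0.73 to 0.50) on the R72 arrays. It was 0.05 ± 0.16 (SD, n = 4, range -0.13 to 0.25) on the p53+/+ arrays and -0.33 ± 0.19 (SD, n = 4, range -0.50 to -0.10) on the p53-/- arrays. No comparison called Trp53. The difference between p53+/+ and p53-/- was 0.23 ± 0.24 (adjusted p = 0.817) untreated and 0.52 ± 0.24 (adjusted p = 0.119) irradiated. A second Trp53 probe at chromosome 11, 69671206 to 69671265 was at -5.36 ± 1.05 (SD, n = 12) in P72 and -5.64 ± 0.97 (SD, n = 12) in R72, where it was well above background on 5 and 6 of the 12 arrays. It was at -0.80 ± 0.24 (SD, n = 4) in p53+/+ and -1.69 ± 0.12 (SD, n = 4) in p53-/-. The sources do not give the deleted or replaced part of the gene, so neither probe checks the labels. Transcripts from the X-inactivation locus Xist separated the arrays by sex. In P72 and R72, replicates 1 and 3 lay between -7.92 and -3.73 and replicates 2 and 4 between 5.11 and 5.83, although the labels give each pool 1 male and 1 female. The 2 untreated p53+/+ arrays (-0.88 and -1.45) were on the male side by the Y-linked genes and the 2 irradiated ones on the female side, and all 4 p53-/- arrays were on the male side.

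The comparison of 2 h with 0 h asks how thymocytes respond to irradiation early. In P72 thymocytes p53 target genes rose within 2 h while genes of mitosis fell. The apoptosis regulator Phlda3 rose by 5.09 ± 0.10, which is 34.2-fold (adjusted p = 3.59e-18, n = 4 against 4). The kinase Plk2 rose by 5.03 ± 0.28 and the cyclin-dependent kinase inhibitor Cdkn1a (p21) by 4.21 ± 0.24. Among p53 targets that promote cell death, Bbc3 (PUMA) rose by 3.44 ± 0.09, Pmaip1 (NOXA) by 3.33 ± 0.19 and Bax by 2.03 ± 0.11. The cytokine Gdf15 rose by 4.41 ± 0.27 and the chemokine Ccl7 by 4.01 ± 0.34. The co-stimulatory ligand Tnfsf4 was not well above background at 0 h and was at least 31.7-fold higher at 2 h. The same holds for 1700007K13Rik and the matrix protein Ccn1, which were at least 37.4-fold and 18-fold higher. Ccnb1 (cyclin B1) fell by 2.16 ± 0.18 on the log2 scale, the aminotransferase Bcat1 by 2.28 ± 0.42 and the growth regulator Myc by 1.71 ± 0.33. The p53 regulator Mdm2 rose by 1.05 ± 0.12, the death receptor Fas by 0.76 ± 0.09 and the inflammatory caspase Casp4 by 1.26 ± 0.23 (adjusted p = 0.00094).

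Gene lists fixed in advance are given as the median log2 change of the list minus that of all genes, with camera's adjusted p at its preset correlation and the number of members called over all genes. In P72 at 2 h the list of p53 targets in apoptosis stood at 1.78 (adjusted p = 2.53e-22), with 16 of 20 members up and 1 down. Its members Aen, an exonuclease, and Trp53inp1 rose by 2.67 ± 0.10 and 0.50 ± 0.07. Targets in the cell cycle, DNA repair and feedback stood at 0.31 (adjusted p = 1.87e-13), with 15 of 24 up and 2 down, among them Ccng1 at 2.77 ± 0.11 and Psrc1 at 2.46 ± 0.12. Metabolic and other p53 targets stood at 0.42 (adjusted p = 1.04e-07), with 9 of 18 up. The G2/M and mitosis list stood at -0.98 (adjusted p = 2.19e-28), with 25 of 30 down, and heat shock genes at -0.46 (adjusted p = 1.32e-05), with 7 of 14 down and 1 up. These 5 calls held with an estimated correlation. Adjusted over the list alone, the numbers up and down were 16 and 2 for apoptosis, 17 and 2 for the cell cycle list, 11 and 1 for metabolism, and 0 and 29 for mitosis.

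The call of another 8 lists in P72 at 2 h was lost with an estimated correlation. Fry tests a list against the spread between arrays and not against other genes, and by it 11 of the 13 calls held. For NF-kB target genes the value was 0.37 (adjusted p = 7.88e-05, and adjusted p = 0.272 with an estimated correlation), with 20 of 46 up and 3 down, and 22 up and 4 down adjusted over the list alone. Their inhibitor Nfkbia was at 0.07 ± 0.10 (adjusted p = 0.696) and the cytokine Tnf at -0.08 ± 0.19 (adjusted p = 0.818). Another member, Ier3, rose by 2.51 ± 0.18. Inflammatory caspases and inflammasome genes stood at 0.57 (adjusted p = 0.00537, and adjusted p = 0.24 with an estimated correlation), with 4 of 16 up, among them Casp1 at 0.59 ± 0.18 (adjusted p = 0.0356). Immediate early genes stood at 0.39 (adjusted p = 1.19e-05, and adjusted p = 0.0964 with an estimated correlation), with 12 of 24 up and 1 down. Glucocorticoid-responsive genes stood at 0.38 (adjusted p = 0.000214, and adjusted p = 0.082 with an estimated correlation), with 7 of 15 up. Replication genes of G1/S stood at -0.22 (adjusted p = 0.00273, and adjusted p = 0.611 with an estimated correlation), with 1 of 25 up and 2 down. Markers of other cell types moved with these lists. Dendritic cell markers stood at 0.59 (adjusted p = 0.000158), neutrophil markers at 0.50 (adjusted p = 0.0179) and thymic epithelial markers at 0.87 (adjusted p = 7.88e-05), with 9 of 15, 1 of 16 and 8 of 14 up. With an estimated correlation their adjusted p = 0.163, adjusted p = 0.637 and adjusted p = 0.272, and the neutrophil list turned to -0.095 on the later scan dates alone.

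In R72 thymocytes the same p53 target lists rose at 2 h and mitotic genes fell. Phlda3 rose by 5.01 ± 0.10, Plk2 by 4.01 ± 0.28, Cdkn1a by 3.33 ± 0.24, Bbc3 by 3.32 ± 0.09, Pmaip1 by 2.72 ± 0.19, Ccng1 by 2.59 ± 0.11 and Bax by 2.21 ± 0.11. Ccl7 rose by 4.14 ± 0.34, Gdf15 by 3.74 ± 0.27 and 9030617O03Rik by 4.00 ± 0.14, and Tnfsf4 and 1700007K13Rik were at least 34.9-fold and 31-fold higher. Mdm2 rose by 0.85 ± 0.12, Fas by 0.83 ± 0.09 and Trp53inp1 by 0.50 ± 0.07. Ccnb1 fell by 1.92 ± 0.18 on the log2 scale and the chaperone Hsph1 by 1.65 ± 0.27. Casp4 was at 0.26 ± 0.23 (adjusted p = 0.501), Casp1 at 0.05 ± 0.18 (adjusted p = 0.884), Tnf at 0.14 ± 0.19 (adjusted p = 0.656) and Nfkbia at -0.08 ± 0.10 (adjusted p = 0.628). Ier3 rose by 1.5 ± 0.18, but turned to -0.28 under normexp, whose fit failed on some arrays, and not with capped background.

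The apoptosis targets stood at 1.76 in R72 at 2 h (adjusted p = 2e-20), with 14 of 20 up and 2 down. The cell cycle, repair and feedback targets stood at 0.39 (adjusted p = 1.49e-15), with 14 of 24 up, metabolic targets at 0.30 (adjusted p = 2.77e-05), with 8 of 18 up and 1 down, and heat shock genes at -0.61 (adjusted p = 3.85e-08), with 7 of 14 down. These 4 calls held with an estimated correlation. The mitosis list stood at -0.76 (adjusted p = 5.07e-22, and adjusted p = 0.0962 with an estimated correlation), with 22 of 30 down, and 27 down adjusted over the list alone. The G1/S list stood at -0.25 (adjusted p = 2.77e-05, and adjusted p = 0.606 with an estimated correlation), with 6 of 25 down, and turned to 0.222 under normexp alone. Immediate early genes stood at 0.26 (adjusted p = 0.00182, and adjusted p = 0.336 with an estimated correlation), with 9 of 24 up, and glucocorticoid-responsive genes at 0.22 (adjusted p = 0.0147, and adjusted p = 0.336 with an estimated correlation). NF-kB target genes stood at 0.10 (adjusted p = 0.151), with 8 of 46 up and 5 down, and neutrophil, dendritic cell and epithelial markers at 0.13, 0.27 and 0.06 (adjusted p = 0.693, adjusted p = 0.276 and adjusted p = 0.875).

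At 2 h the limma fit called 1978 genes up and 988 down in P72 and 1264 up and 1411 down in R72, of 20534 tested, of which 953 and 63 in P72 and 509 and 80 in R72 changed at least 2-fold. The balance moved with the scaling: centred on the array median 47.2% of the calls were up in P72 and 34.2% in R72, against 66.7% and 47.3%. By the values the authors tabulated, 50.6% of 1847 were up in P72. Normexp called 498 genes in P72 and 361 in R72, and with the background capped 1495 and 1409. A fixed block for the slide called 2296 genes in P72 and 3711 in R72. Of genes called without the arrays of a slide, 95.9% to 97% in P72 and 85.8% to 97.9% in R72 went the same way within that slide. R72 lost calls to 1626 without R72 0 h replicate 3. Across genes the changes of P72 and R72 correlated with r = 0.705. Both genotypes called 764 genes up and 691 down, where independent lists would share 121.8 and 67.9, and 0 genes went opposite ways.

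**Figure D1:**
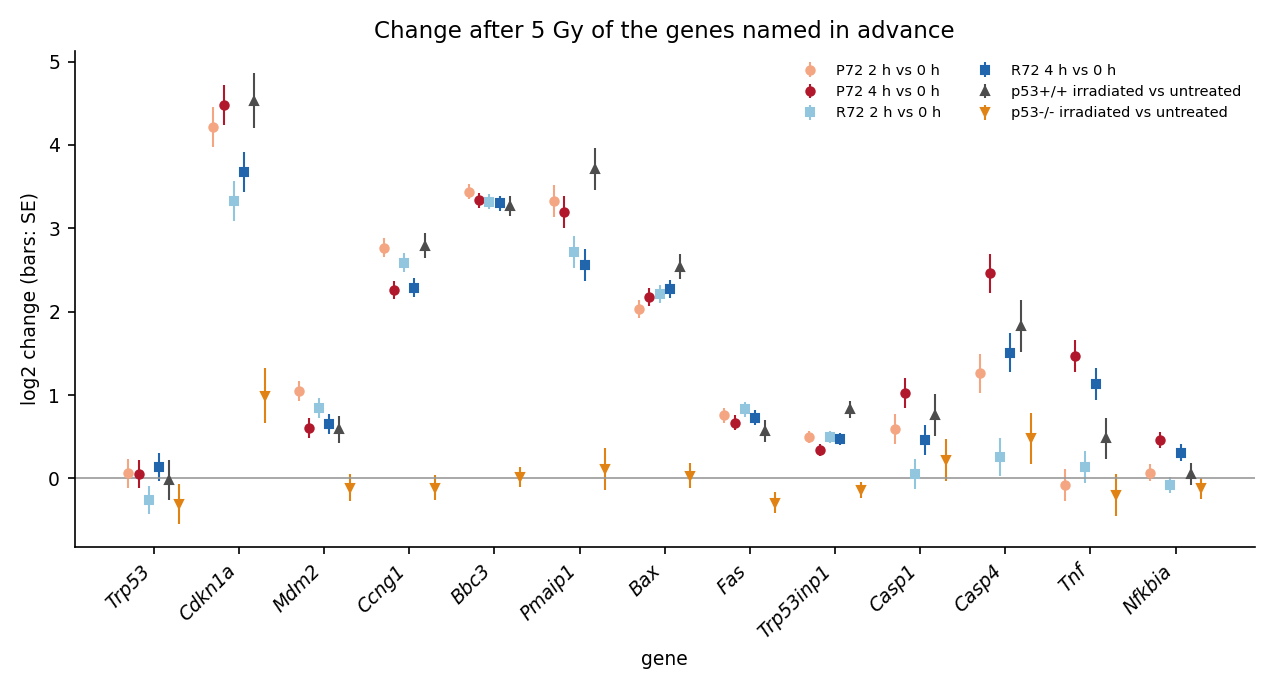
Log2 change (y axis) of the 13 genes named in advance (x axis) after 5 Gy, in P72 and R72 at 2 h and 4 h and in p53+/+ and p53-/- over both times, with standard errors as bars. Bbc3 lies between 3.27 and 3.44 in P72, R72 and p53+/+ and at 0.02 in p53-/-.

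The comparison of 4 h with 0 h asks how the response had developed. By 4 h chemokines and other inflammatory genes had risen in P72 beside the p53 targets, and replication genes had fallen. Ccl7 rose by 6.36 ± 0.34, Ccl2 by 5.88 ± 0.30, Ccl3 by 4.58 ± 0.28 and the cytokine Il1b by 5.41 ± 0.30. The interferon-inducible gene Ifi202b rose by 6.25 ± 0.52, the stress-induced transcription factor Atf3 by 4.78 ± 0.21 and Ier3 by 4.76 ± 0.18. Tnf rose by 1.47 ± 0.19 (adjusted p = 2.59e-06), Casp4 by 2.46 ± 0.23, Casp1 by 1.02 ± 0.18 and Nfkbia by 0.46 ± 0.10. Phlda3 stood at 4.50 ± 0.10, Cdkn1a at 4.48 ± 0.24, Bbc3 at 3.34 ± 0.09, Pmaip1 at 3.20 ± 0.19 and Bax at 2.18 ± 0.11, all past the threshold. Bcat1 fell by 3.64 ± 0.42 on the log2 scale, the folate enzyme Shmt1 by 2.64 ± 0.20, Hsph1 by 2.58 ± 0.27 and the uracil glycosylase Ung by 2.22 ± 0.15. The replication genes Mcm2 and Pcna fell by 1.34 ± 0.11 and 1.19 ± 0.10. The deaminase Dctd was at least 3.05-fold lower, but turned to 0.18 under normexp alone. Between 0 h and 4 h the median of all genes moved by 0.106 in P72 and 0.093 in R72 at this scaling, and list medians are given relative to that shift.

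In P72 at 4 h apoptosis targets stood at 1.83 (adjusted p = 1.7e-06), with 16 of 20 up and 3 down, and this was the only 1 of 18 calls that held with an estimated correlation. The NF-kB target genes were at 0.98 (adjusted p = 3.04e-09, and adjusted p = 0.112 with an estimated correlation), with 36 of 46 up and 3 down, and 38 up and 3 down adjusted over the list alone. Inflammasome genes stood at 0.97 (adjusted p = 0.00612, and adjusted p = 0.217 with an estimated correlation), with 12 of 16 up and 2 down, among them the pyrin gene Mefv at 2.53 ± 0.23. Toll-like receptor and sensing genes stood at 0.68 (adjusted p = 0.000948, and adjusted p = 0.129 with an estimated correlation), with 16 of 22 up and 1 down, among them the co-receptor Cd14 at 2.99 ± 0.29 and Tlr2 at 1.73 ± 0.13. Immediate early genes stood at 0.80 (adjusted p = 0.000116, and adjusted p = 0.14 with an estimated correlation), with 18 of 24 up and 4 down. Interferon-stimulated genes stood at 0.39 (adjusted p = 0.00978, and adjusted p = 0.472 with an estimated correlation), with 22 of 36 up and 2 down, and at -0.008 with no filter on dim probes. Markers of other cell types rose with these lists, and none of their calls held with an estimated correlation. Dendritic cell markers stood at 1.11 (adjusted p = 0.000594), with 11 of 15 up, and neutrophil markers at 1.40 (adjusted p = 0.000201), with all 16 up. Macrophage markers stood at 0.77 (adjusted p = 0.00108), with 14 of 19 up, and thymic epithelial markers at 1.18 (adjusted p = 0.00182), with 11 of 14 up. Their adjusted p with an estimated correlation was 0.181, 0.339, 0.354 and 0.339. Examples of these markers are the integrin Itgax at 1.81 ± 0.21, the neutrophil receptor Cxcr2 at 2.41 ± 0.36 and the keratin Krt18 at 2.17 ± 0.23.

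Genes of the cell cycle fell in P72 at 4 h. The G1/S and replication list stood at -1.08 (adjusted p = 3.8e-14), with 24 of 25 down, and the mitosis list at -0.97 (adjusted p = 8.62e-14), with all 30 down. Their adjusted p with an estimated correlation was 0.112 and 0.169. Heat shock genes stood at -0.81 (adjusted p = 0.000149, and adjusted p = 0.1 with an estimated correlation), with 9 of 14 down and 2 up, among them Hsp90aa1 at -1.54 ± 0.12. The remaining p53 targets stood at 0.31 for cell cycle and repair (adjusted p = 0.000594), with 16 of 24 up and 3 down, and at 0.59 for metabolism (adjusted p = 0.00528), with 10 of 18 up and 2 down. Both had adjusted p = 0.1 with an estimated correlation. With no filter on dim probes the cell cycle and repair targets turned to -0.089 and the glucocorticoid-responsive genes, at 0.30 (adjusted p = 0.0173, and adjusted p = 0.229 with an estimated correlation), to -0.103. Markers of double positive thymocytes, the main stage of the thymus, stood at -0.32 (adjusted p = 0.0102, and adjusted p = 0.229 with an estimated correlation), with 8 of 18 down and 2 up, among them the pre-T-cell receptor gene Ptcra at -1.01 ± 0.13. Their median was at percentile 36.7 of lists matched on level. Markers of mature single positive thymocytes stood at 0.45 (adjusted p = 0.0404, and adjusted p = 0.43 with an estimated correlation), with 13 of 21 up and 2 down.

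In R72 at 4 h chemokine and p53 target genes rose as well and replication genes fell. Ccl7 rose by 5.92 ± 0.34, Ccl2 by 5.21 ± 0.30, Il1b by 4.25 ± 0.30, Ccl3 by 4.06 ± 0.28, Atf3 by 3.94 ± 0.21, Ier3 by 3.60 ± 0.18, Casp4 by 1.51 ± 0.23, Tnf by 1.13 ± 0.19 and Nfkbia by 0.31 ± 0.10 (adjusted p = 0.0133). Phlda3 rose by 4.73 ± 0.10, Cdkn1a by 3.68 ± 0.24, Bbc3 by 3.30 ± 0.09 and Pmaip1 by 2.56 ± 0.19. The coagulation factor gene F3 was at least 17.3-fold higher. Bcat1 fell by 3.58 ± 0.42 on the log2 scale, Shmt1 by 2.78 ± 0.20, the receptor gene Gfra1 by 2.73 ± 0.24, Mcm2 by 1.19 ± 0.11 and Pcna by 1.17 ± 0.10. The neutrophil genes Cxcr2 and Csf3r were at 0.84 ± 0.36 (adjusted p = 0.0629) and 0.70 ± 0.33 (adjusted p = 0.0919).

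Apoptosis targets in R72 at 4 h stood at 1.31 (adjusted p = 8.41e-08), with 16 of 20 up and 3 down, and cell cycle and repair targets at 0.42 (adjusted p = 1.52e-05), with 15 of 24 up and 3 down. These 2 calls held with an estimated correlation. The NF-kB target genes were at 0.56 (adjusted p = 8.41e-08, and adjusted p = 0.144 with an estimated correlation), with 34 of 46 up and 3 down, and 36 up and 3 down adjusted over the list alone. Immediate early genes stood at 0.61 (adjusted p = 3.07e-05), inflammasome genes at 0.57 (adjusted p = 0.0247) and sensing genes at 0.45 (adjusted p = 0.0208). Their adjusted p with an estimated correlation was 0.144, 0.309 and 0.287. The G1/S list stood at -1.0 (adjusted p = 2.59e-18, and adjusted p = 0.0824 with an estimated correlation), with 24 of 25 down, and the mitosis list at -0.75 (adjusted p = 8.77e-12, and adjusted p = 0.246 with an estimated correlation), with 25 of 30 down. Heat shock genes stood at -0.61 (adjusted p = 8.36e-05), metabolic p53 targets at 0.27 (adjusted p = 0.012) and glucocorticoid-responsive genes at 0.26 (adjusted p = 0.0141). Their adjusted p with an estimated correlation was 0.0824, 0.104 and 0.246. Dendritic cell markers stood at 0.65 (adjusted p = 0.00838, and adjusted p = 0.309 with an estimated correlation), with 10 of 15 up. Neutrophil, macrophage and epithelial markers stood at 0.54, 0.34 and 0.56 (adjusted p = 0.116, adjusted p = 0.104 and adjusted p = 0.103), and interferon-stimulated genes at 0.21 (adjusted p = 0.103).

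**Figure D2:**
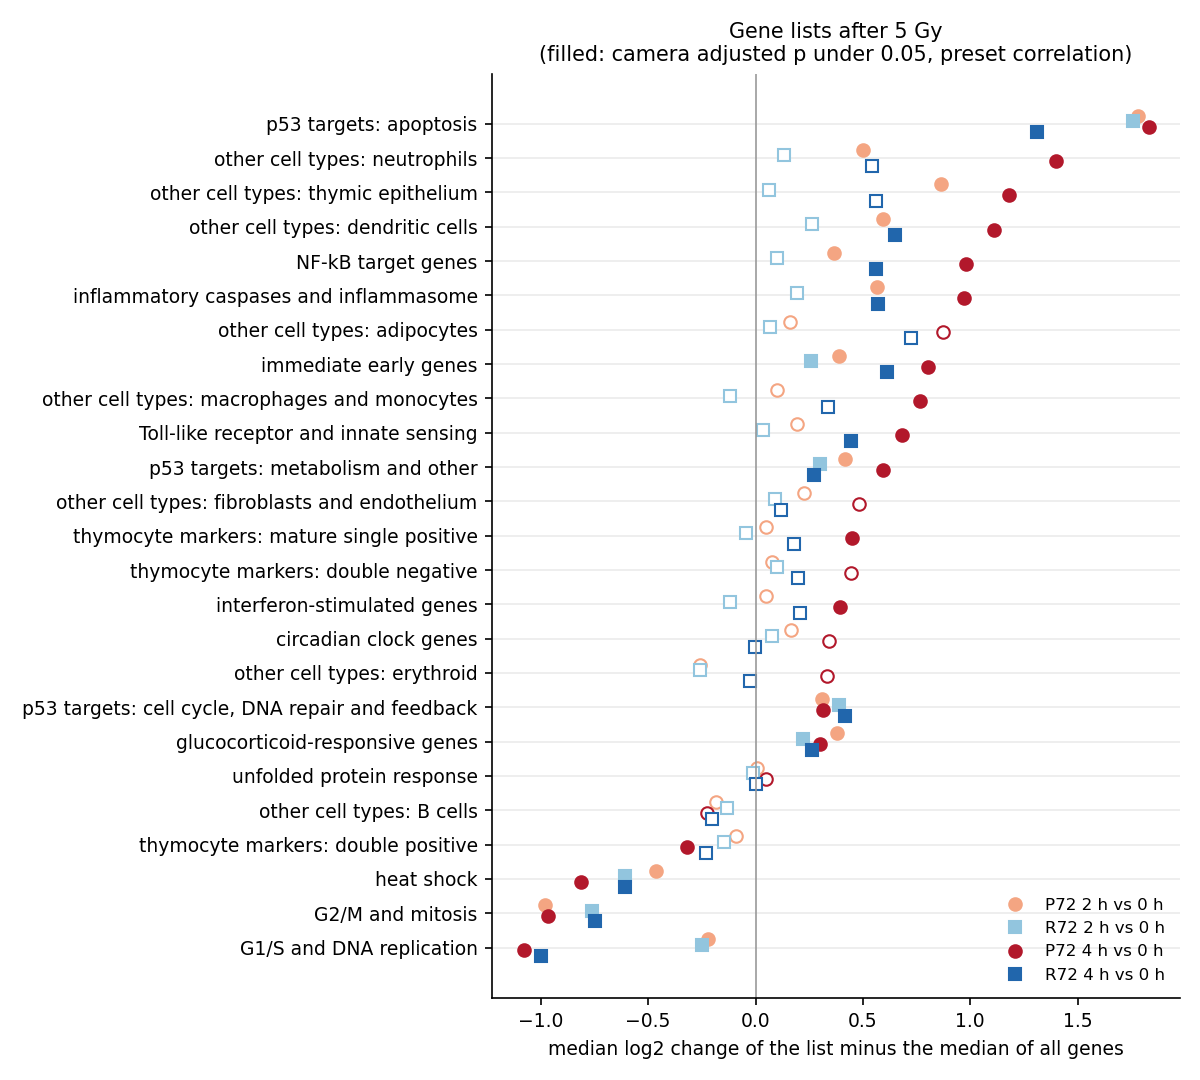
Median log2 change of each gene list minus that of all genes (x axis) for the lists (y axis) at 2 h and 4 h in P72 and R72, filled where camera's adjusted p with the preset correlation was under 0.05. The G1/S list lies at -0.22 and -0.25 at 2 h and at -1.08 and -1.0 at 4 h.

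At 4 h 7368 genes were called up and 4253 down in P72 (4871 and 345 at least 2-fold), and 5914 up and 3296 down in R72 (3596 and 215 at least 2-fold). The share of calls that were up was 63.4% and 64.2%. Centred on the array median it was 46% and 47.1%, and by the authors' tabulated values 48.7% and 51.4%. With only probes well above background on every array the calls were 3465 up and 4096 down in P72 and 2685 up and 3219 down in R72, and normexp called 5820 and 1324 genes. Among genes ranked by mean signal, the dimmest of 3 equal parts had a median change of 1.18 in P72 and 0.89 in R72, and the brightest -0.16 and -0.12. With a fixed block for the slide 11241 genes were called in P72 and 9340 in R72. Of genes called without a slide's arrays, 9209 of 9449 and 8934 of 9039 went the same way within the 2 slides in P72, and 97.7% and 98.8% in R72. Across genes the changes in P72 and R72 correlated with r = 0.926. Both genotypes called 5537 genes up and 2976 down, where independent lists would share 2122.1 and 682.7, and 3 went opposite ways.

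Between 2 h and 4 h inflammatory genes rose and replication genes fell in both genotypes. Tnf rose by 1.55 ± 0.19 in P72 and 0.99 ± 0.19 in R72, Casp4 by 1.20 ± 0.23 and 1.25 ± 0.23, Nfkbia by 0.40 ± 0.10 and 0.39 ± 0.10, and Ifi202b by 4.25 ± 0.52 and 4.66 ± 0.52. The chemokine gene Cxcl1 was at least 8.78-fold higher in P72, and in R72 the kinase Pdk4 rose by 3.43 ± 0.41 and F3 by 3.95 ± 0.39. In P72 Mdm2 fell by 0.45 ± 0.12 on the log2 scale and Ccng1 by 0.51 ± 0.11. NF-kB target genes stood at 0.58 in P72 (adjusted p = 6.04e-13), with 35 of 46 up and 1 down, and at 0.51 in R72 (adjusted p = 2.56e-13), with 30 up. The G1/S list stood at -0.88 (adjusted p = 9.98e-21) and -0.77 (adjusted p = 1.08e-24), with 24 and 23 of 25 down. With an estimated correlation both lists had adjusted p = 0.112 in P72 and adjusted p = 0.0995 in R72. Apoptosis targets stood at -0.18 in P72 (adjusted p = 0.0282, and adjusted p = 0.189 with an estimated correlation) and -0.13 in R72 (adjusted p = 0.0209, and adjusted p = 0.193 with an estimated correlation), at percentiles 23.1 and 30.1 of lists matched on level. Mitotic genes stood at -0.05 (adjusted p = 0.214) and 0.08 (adjusted p = 0.721), the second turning to -0.176 on the later scan dates alone.

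From 2 h to 4 h 4411 genes were called up and 2174 down in P72, and 3299 up and 999 down in R72, of which 2287 and 63, and 1662 and 26, changed at least 2-fold. Centred on the median the P72 calls were 45.2% up, against 67%, and the R72 calls 56.6%, against 76.8%. By the authors' tabulated values they were 52.5% and 56.4% up. Normexp called 879 and 398 genes, with the background capped 4073 and 7406, and the first scan date alone 1479 and 58. With the slide as a fixed block 7771 and 5139 genes were called. Within a slide left out of the calls 90.5% to 98.8% of the called genes kept their direction in P72 and 90.9% to 95.4% in R72. R72 calls fell to 2828 without R72 2 h replicate 4 and to 2207 without R72 4 h replicate 2. Among the genes that fell most, Lrrc75a in P72 (-1.80 ± 0.29) and Klf15 in R72 (-1.70 ± 0.36) turned to 0.20 and 0.64 under normexp, and Klf15 to 0.23 with the local background capped.

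The p53+/+ and p53-/- arrays ask which part of the response needs p53. Among these arrays only the irradiated p53+/+ ones were on the female side. Sex therefore goes with irradiation in p53+/+, with genotype after irradiation and with the difference of the responses. With a block for sex, 147 list results over all comparisons kept their side of the threshold. So did 468 named-gene results, while 6 lost the call and 1 gained it. Most were of P72 and R72, whose groups held both sexes equally. For p53+/+ the block removes only a sex effect shared with them, so sex stays open. In irradiated p53+/+ thymocytes, 2 h and 4 h together, p53 target genes rose that were not called in p53-/-. In p53+/+ Plk2 rose by 6.37 ± 0.41, Phlda3 by 5.17 ± 0.14, Cdkn1a by 4.53 ± 0.33, Pmaip1 by 3.71 ± 0.25, Bbc3 by 3.27 ± 0.12, Ccng1 by 2.79 ± 0.15 and Bax by 2.54 ± 0.15. Tnfsf4 and 1700007K13Rik were at least 78.4-fold and 132-fold higher. The stress ligand gene H60 rose by 8.57 ± 0.53 in p53+/+ but was not called in P72 (-0.51 at 2 h and 0.36 at 4 h) or R72 (-0.04 and 0.52). Ccl2 rose by 3.96 ± 0.41, Il1b by 3.84 ± 0.41 and Casp4 by 1.83 ± 0.31, while Tnf was at 0.48 ± 0.25 (adjusted p = 0.167) and Nfkbia at 0.05. Hsph1 fell by 2.83 ± 0.36 on the log2 scale, Bcat1 by 2.70 ± 0.56 and Ccnb1 by 1.76 ± 0.24. In p53-/- Cdkn1a was at 0.99 ± 0.33 (adjusted p = 0.173), Pmaip1 at 0.11, Bax at 0.03 and Bbc3 at 0.02. The oligopeptide transporter gene Slc15a2 rose by 8.27 ± 1.11 in p53-/- (adjusted p = 0.00112), while its level ranged from -3.28 to 1.87 within p53+/+. Also in p53-/- Ccl2 rose by 2.30 ± 0.41, the interferon-stimulated gene Isg15 by 1.38 ± 0.22, the replication factor Cdc6 by 0.98 ± 0.16 and Ccne1 (cyclin E1) by 0.73 ± 0.14. The test of the difference between the responses called Phlda3 at 5.22 ± 0.20, Pmaip1 at 3.60 ± 0.36, Cdkn1a at 3.54 ± 0.47, Bbc3 at 3.25 ± 0.17, Ccng1 at 2.89 ± 0.21, Bax at 2.52 ± 0.21, Trp53inp1 at 0.97 ± 0.14 and Fas at 0.86 ± 0.18. Casp4 at 1.34 ± 0.44 (adjusted p = 0.0804) and Mdm2 at 0.70 ± 0.23 (adjusted p = 0.0786) did not pass it.

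In p53+/+ after irradiation apoptosis targets stood at 2.12 (adjusted p = 3.8e-15), with 14 of 20 up and 2 down, cell cycle and repair targets at 0.29 (adjusted p = 8.22e-08), metabolic targets at 0.53 (adjusted p = 1.03e-05) and heat shock genes at -0.98 (adjusted p = 6.18e-07). These 4 calls held with an estimated correlation. NF-kB target genes stood at 0.31 (adjusted p = 0.00283), with 13 of 46 up and 3 down. Neutrophil markers rose beside them at 1.04 (adjusted p = 0.000464). Both had adjusted p = 0.516 with an estimated correlation. Replication genes of G1/S stood at -0.37 (adjusted p = 0.00199, and adjusted p = 0.541 with an estimated correlation) and turned to 0.048 without the p53+/+ 4 h array. In p53-/- the G1/S list stood at 0.50 (adjusted p = 1.49e-19, and adjusted p = 0.233 with an estimated correlation), with 6 of 25 up, and 18 up adjusted over the list alone. Interferon-stimulated genes stood at 0.29 (adjusted p = 1.41e-06) and double positive markers at -0.27 (adjusted p = 0.000726). With an estimated correlation these had adjusted p = 0.634 and 0.314. NF-kB target genes stood at -0.03 (adjusted p = 0.814), turning to 0.093 without the p53-/- 2 h array. The difference between the 2 responses was 1.68 for apoptosis targets (adjusted p = 2.62e-20), 0.59 for cell cycle and repair targets (adjusted p = 3.08e-11), 0.55 for metabolic targets (adjusted p = 2.16e-06) and -0.80 for heat shock genes (adjusted p = 7.34e-06), and these 4 calls held with an estimated correlation. It was -0.82 for the G1/S list (adjusted p = 7.34e-16) and 0.22 for NF-kB target genes (adjusted p = 0.00238). With an estimated correlation these had adjusted p = 0.0931 and 0.571.

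Set directly against irradiated p53-/-, irradiated p53+/+ thymocytes were higher by 9.72 ± 0.53 for H60 (not called in P72 or R72), 6.42 ± 0.41 for Plk2, 6.17 ± 0.14 for Phlda3, 4.04 ± 0.12 for Bbc3, 3.80 ± 0.33 for Cdkn1a and 3.21 ± 0.43 for Ccl3. Myc was lower by -2.50 ± 0.45 and the B-cell gene Vpreb3 by -3.80 ± 0.35. The same lists stood apart: apoptosis at 1.81 (adjusted p = 1.96e-17), cell cycle and repair at 0.68 (adjusted p = 1.87e-10) and metabolism at 0.58 (adjusted p = 5.38e-05), all holding with an estimated correlation, and G1/S at -0.76 (adjusted p = 8.92e-15, and adjusted p = 0.142 with an estimated correlation). NF-kB target genes stood at 0.20 (adjusted p = 0.0279, and adjusted p = 0.691 with an estimated correlation), turning to -0.123 with no filter and to -0.058 without the p53+/+ 4 h array. Untreated, p53+/+ was higher by 0.95 ± 0.14 for Phlda3, 0.79 ± 0.12 for Bbc3 and 1.00 ± 0.21 for the RNA-binding p53 target Zmat3, and lower by -3.89 ± 0.35 for Vpreb3 and -1.15 ± 0.25 for Tnf (adjusted p = 0.0288). Apoptosis targets stood at 0.14 there (adjusted p = 0.00721) and B-cell markers at -0.81 (adjusted p = 5.48e-08). Both had adjusted p = 0.135 with an estimated correlation.

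The fits with all 32 arrays tested 20526 genes. They called 2660 up and 2179 down in p53+/+ after irradiation (1715 and 200 at least 2-fold) and 147 up and 69 down in p53-/- (65 and 3 at least 2-fold). Between the genotypes they called 71 up and 74 down untreated (49 and 35 at least 2-fold) and 2679 up and 1804 down irradiated (1865 and 196 at least 2-fold). The responses differed for 635 genes higher and 454 lower (501 and 142 at least 2-fold). Centred on the median the shares called up were 33.4% in p53+/+, 43.2% between irradiated genotypes and 38.2% for the difference, against 55%, 59.8% and 58.3%. With the slide as a fixed block the counts were 4527, 163, 198, 1352 and 469, in that order, and under normexp 1017, 22, 15, 922 and 228. Single arrays weighed heavily, since each irradiated group held 1 array and was assumed to vary like the others. Without the p53+/+ 4 h array the p53+/+ response called 1219 genes, the irradiated difference 694 and the difference of responses 305. Without the p53+/+ 2 h array these were 5969, 5792 and 2281, and without the p53-/- 2 h array the irradiated difference called 1362 genes, the difference of responses 353 and the p53-/- response 45. Without untreated p53+/+ replicate 1 or 2 the p53+/+ response called 2896 or 2475 genes and the untreated difference 33 or 41, and without replicate 2 the difference of responses called 514. Without untreated p53-/- replicate 1 or 2 the untreated difference called 29 or 45, the p53-/- response 23 or 33 and the difference of responses 507 or 451.

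The 634 genes that rose more in p53+/+ than in p53-/- and were higher after irradiation gave a list of p53-dependent radiation-induced genes, of which the 100 with the smallest p were measured on the P72 and R72 arrays, whose changes were not used to choose them, although the spread of all 32 arrays entered those p. Of the 100, 24 were also in the p53 target lists. In P72 their median change was 1.73 at 2 h, with 98 up and 0 down, and 1.95 at 4 h, with 98 up. In R72 it was 1.59 at 2 h, with 96 up, and 1.62 at 4 h, with 99 up. An exact two-sided permutation of 4 against 4 arrays gave p = 0.0286 for the list mean in each of these, the smallest p it allows, beside camera's p = 4.05e-130 and p = 1.11e-46 in P72 and p = 1.34e-128 and p = 9.59e-57 in R72. Within single slides the list stood, relative to all genes, between 1.67 and 1.75 in P72 and between 1.44 and 1.72 in R72. From 2 h to 4 h the median was 0.05 in P72 (31 up and 23 down) and -0.03 in R72 (26 up and 20 down).

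**Figure D3:**
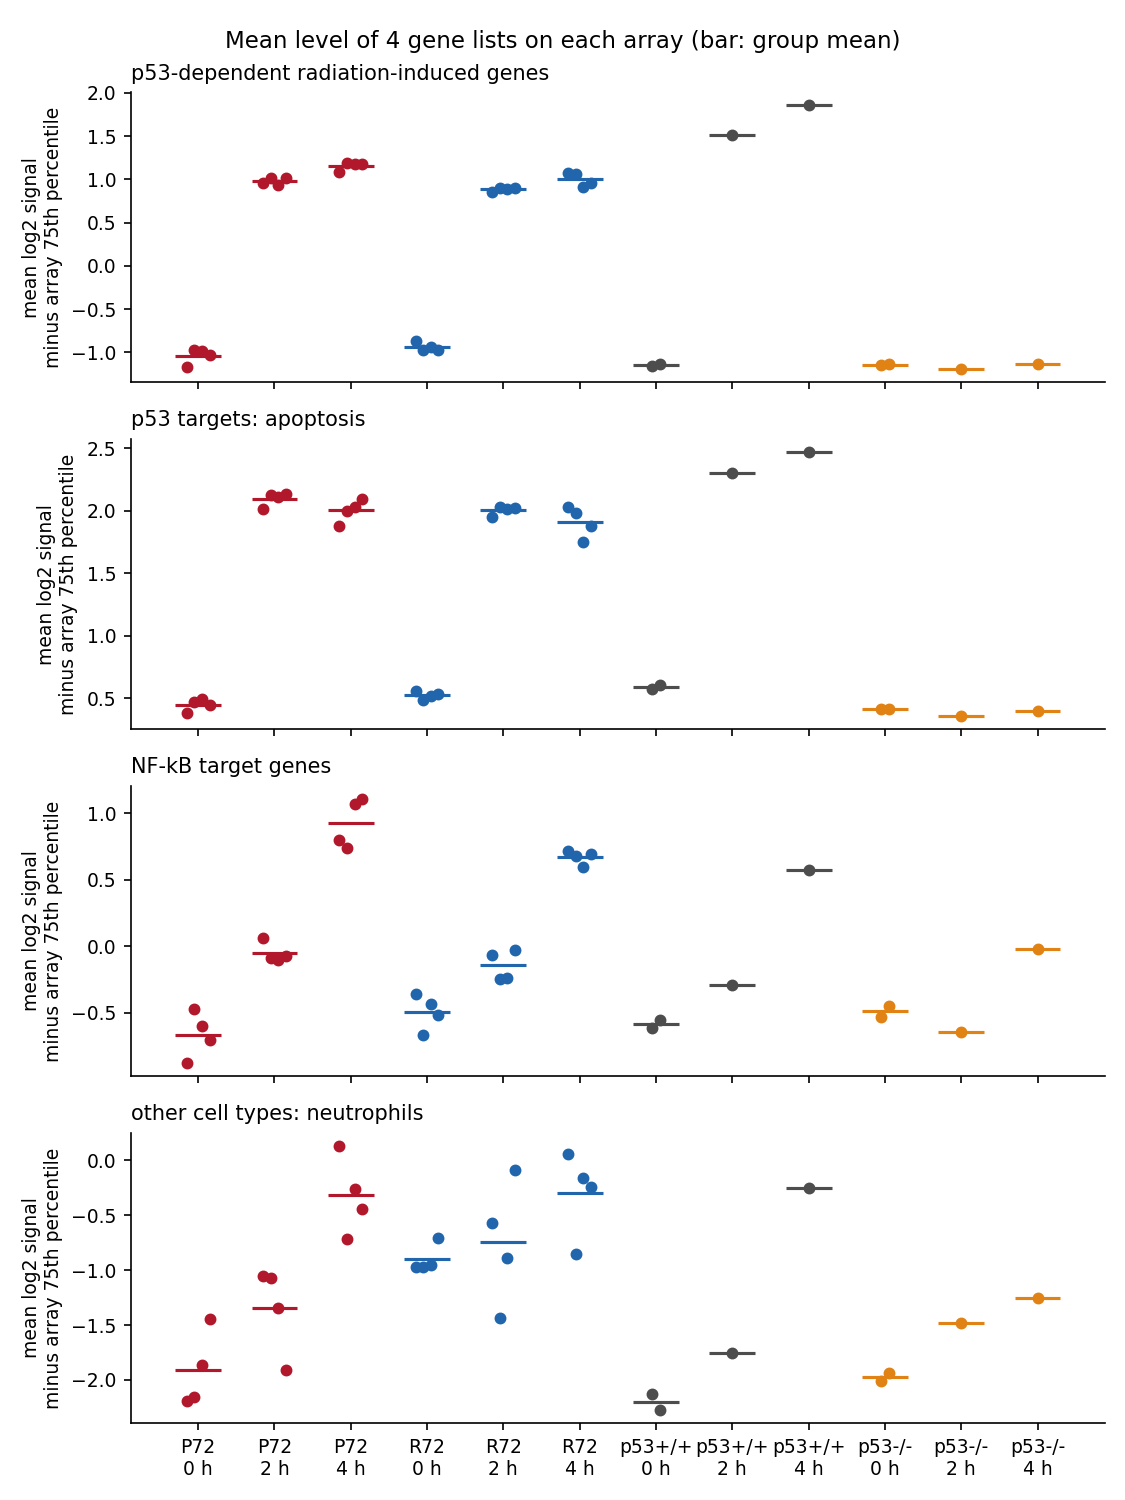
Mean level of 4 gene lists (y axis, log2 signal minus the array's 75th percentile) on each array, by genotype and time (x axis), with group means as bars. The neutrophil list means were -1.91 in P72 and -0.90 in R72 at 0 h and -0.32 and -0.30 at 4 h.

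The comparison of P72 with R72 asks which genes differ between the codon 72 variants. A small set of genes differed at every time, with and without irradiation. Over all 3 times together the small GTPase gene Rab6b was higher in P72 by 5.66 ± 0.55 (adjusted p = 1.75e-06, n = 12 against 12), the transcriptional regulator Prdm16 by 4.06 ± 0.26, Zfp933 by 2.67 ± 0.17, the lymphoid antigen Ly6d by 2.20 ± 0.23, Depdc6 by 2.04 ± 0.23 and Ica1 by 1.80 ± 0.20. Greb1 was at least 16.4-fold lower in P72 (adjusted p = 2.24e-11). Lypd1 stood at -2.90 ± 0.33, the potassium channel Kcnf1 at -2.65 ± 0.32, asparagine synthetase Asns at -2.39 ± 0.09 (adjusted p = 9.97e-13), Adi1 at -1.84 ± 0.10 and Rab4a at -1.63 ± 0.16. The probes lie at chromosome 9, 102899312 to 102899371 for Rab6b, chromosome 6, 7628080 to 7628139 for Asns and 8588810 to 8588869 for Ica1, and chromosome 12, 16726515 to 16726574 for Greb1, 17227061 to 17227120 for Kcnf1 and 26522190 to 26522249 for Adi1 (mm7). Of the genes named in advance, Tnf was at 0.35 ± 0.11 (adjusted p = 0.0443) and Bbc3 at 0.16 ± 0.05 (adjusted p = 0.0439). Casp4 was at 0.37 (adjusted p = 0.0883), Casp1 at 0.27 (adjusted p = 0.109), Cdkn1a at 0.20 (adjusted p = 0.377), Mdm2 at 0.04 and Nfkbia at -0.02. Over all times 1140 genes were higher and 821 lower, of which 90 and 84 differed at least 2-fold. Of those with a coordinate 71.3% had another within 5 Mb, against a median of 56.3% in random sets of genes.

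At 0 h 61 genes were higher in P72 and 125 lower, at 2 h 135 and 128, and at 4 h 138 and 118, of which 28 and 62, 52 and 54, and 47 and 40 differed at least 2-fold. Prdm16 stood at 4.37 ± 0.45, 4.13 ± 0.45 and 3.68 ± 0.45 at the 3 times and Rab6b at 4.33 ± 0.95, 5.78 ± 0.95 and 6.86 ± 0.95. Greb1 was at least 21.8-fold, 14-fold and 14.3-fold lower in P72, and the non-classical MHC gene H2-T3 stood at -7.78 ± 1.54 at 0 h and was at least 77.4-fold lower at 2 h, although 2 R72 arrays were as low as P72. At 2 h Thyn1, a nuclear protein of thymocytes, was higher in P72 by 1.62 ± 0.18 (adjusted p = 2.59e-05). At 4 h P72 was higher for the macrophage receptor Cd163 by 1.54 ± 0.33 (adjusted p = 0.0218), Gdf15 by 1.25 ± 0.27 (adjusted p = 0.025) and the immediate early gene Jun by 0.74 ± 0.17 (adjusted p = 0.0379), and lower for the co-chaperone Dnaja1 by -0.57 ± 0.13 (adjusted p = 0.0275). Casp4 was at 0.67 (adjusted p = 0.187) and Tnf at 0.65 (adjusted p = 0.0967) at 4 h. 8030498J20Rik, at least 3.91-fold higher in P72 at 0 h, turned to -0.08 under normexp alone.

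Slides and genotype overlapped, and only 2 slides held P72 and R72 at one time point, 2 h. On both the P72 array was on the female side and the R72 array on the male side, so sex went with genotype. Of genes called at 2 h without the arrays of such a slide, 128 and 87 in number, 89.8% and 92% went the same way within it. With the slide as a fixed block the counts were 17 at 0 h, 98 at 2 h, 14 at 4 h and 130 over all times. The first scan date, which held all 6 groups with 2 arrays each, called 12, 7, 4 and 361 genes alone, and the later scan dates 55, 279, 98 and 2063. Normexp called 14, 38, 18 and 346, while at 4 h the authors' values called 496 and quantile normalization 469. The share called up at 0 h was 32.8%. At 4 h it was 53.9%, against 42.7% centred on the median. The counts moved without single arrays: at 0 h to 123, 78 and 96 without P72 replicates 1, 3 and 4 and to 96, 123 and 83 without R72 replicates 2, 3 and 4. At 2 h they moved to 166, 160 and 112 without P72 replicates 1, 2 and 4 and to 465 and 141 without R72 replicates 1 and 4. At 4 h they moved to 166, 145, 144 and 112 without P72 replicates 1, 2, 3 and 4 and to 169 and 106 without R72 replicates 2 and 4.

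**Figure D4:**
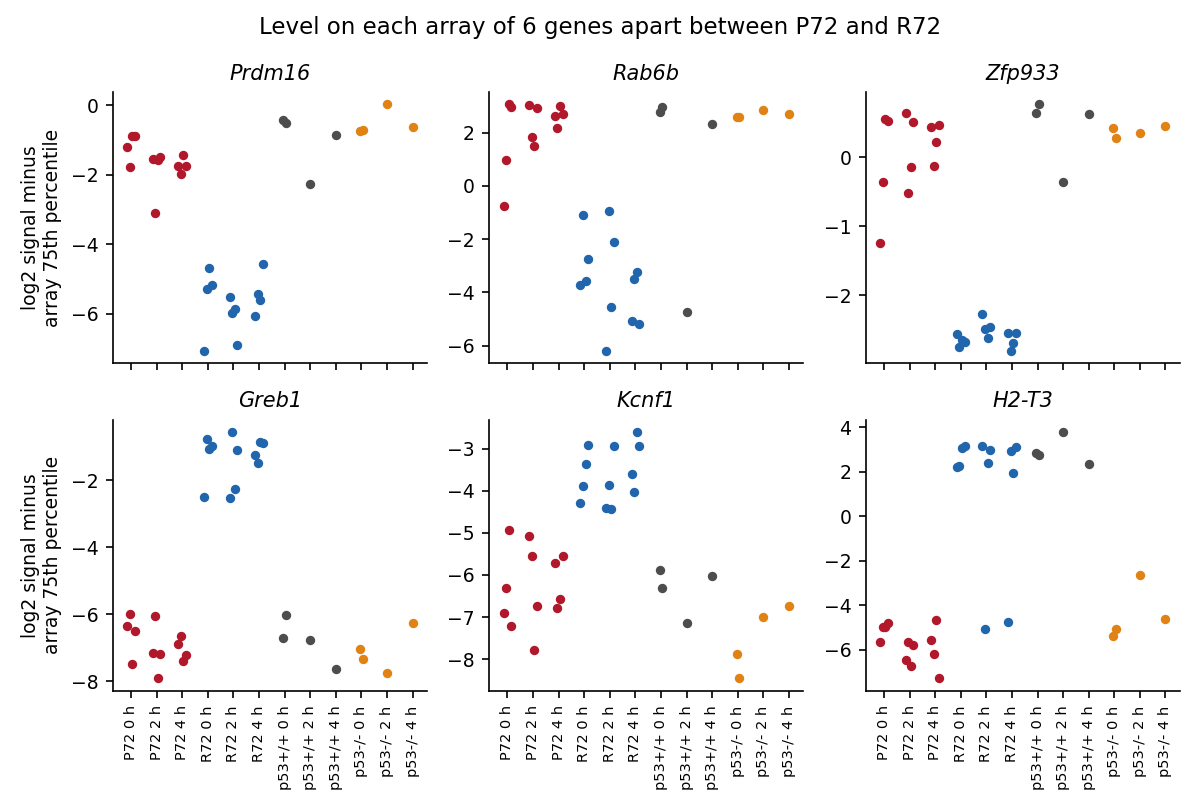
Level (y axis, log2 signal minus the array's 75th percentile) of 6 genes apart between P72 and R72 on each array, by genotype and time (x axis), 1 point per array. Over all times Prdm16 was higher in P72 by 4.06 and Kcnf1 stood at -2.65.

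Between the codon 72 genotypes none of the calls of the lists fixed in advance held with an estimated correlation. At 0 h neutrophil markers stood at -0.99 (adjusted p = 1.95e-16, and adjusted p = 0.254 with an estimated correlation), with 0 of 16 called over all genes and 15 lower adjusted over the list alone. NF-kB target genes stood at -0.13 there (adjusted p = 0.00169, and adjusted p = 0.401 with an estimated correlation), interferon-stimulated genes at -0.21 (adjusted p = 5.08e-05) and epithelial markers at -0.63 (adjusted p = 1.22e-06). Single positive markers stood at -0.22 (adjusted p = 0.00265) and B-cell markers at 0.28 (adjusted p = 0.00204). With an estimated correlation these 4 had adjusted p = 0.401, and under uncapped normexp 3 turned, to 0.061 for interferon, 0.064 for single positive and -0.175 for B-cell genes. At 2 h neutrophil markers stood at -0.62 (adjusted p = 1.42e-05, and adjusted p = 0.86 with an estimated correlation), and at -0.52 and -1.08 within the 2 slides. At 4 h NF-kB target genes stood at 0.17 (adjusted p = 0.000391, and adjusted p = 0.342 with an estimated correlation), with 0 of 46 called over all genes and 4 higher adjusted over the list alone. Their list mean differed by 0.26, with p = 0.0286 in an exact permutation test and 0.154 after adjustment over the lists. Macrophage markers stood at 0.34 (adjusted p = 1.32e-05), dendritic cell markers at 0.42 (adjusted p = 0.00387) and double negative thymocyte markers at 0.42 (adjusted p = 2.64e-05), each with adjusted p = 0.342 with an estimated correlation. Mitotic genes stood at -0.23 (adjusted p = 8.39e-07, and adjusted p = 0.366 with an estimated correlation) and turned to 0.014 on the later scan dates alone. Over all times neutrophil markers stood at -0.49 (adjusted p = 1.24e-07, and adjusted p = 0.796 with an estimated correlation), with 5 of 16 lower.

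The median of the p53-dependent list between P72 and R72 was -0.07 at 0 h (camera p = 0.013, and p = 0.203 with an estimated correlation), 0.10 at 2 h (p = 0.02, and p = 0.232 with an estimated correlation), 0.13 at 4 h (p = 8.45e-06, and p = 0.0293 with an estimated correlation) and 0.07 over all times (p = 0.0348, and p = 0.277 with an estimated correlation). Relative to all genes it was -0.064 at 0 h and 0.061 at 2 h, turning to 0.061 and -0.039 under normexp, and 0.055 over all times, turning to -0.005 with no filter and -0.003 with the capped background. At 2 h the value relative to all genes within the 2 slides was 0.13 and 0.03.

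The difference between the P72 and R72 responses asks whether codon 72 changes what irradiation does. Single genes hardly passed this test. At 2 h the limma test called Thyn1 alone, which rose by 1.74 ± 0.18 in P72 and stood at 0.09 ± 0.18 in R72, a difference of 1.65 ± 0.25 (adjusted p = 0.0351). In arrays looked up after that call, Thyn1 rose by 1.77 ± 0.24 in p53+/+ and was at 0.15 ± 0.24 in p53-/-. The call was lost without any 1 of 13 of the 16 arrays, which left 0 genes, and under several other settings. Unadjusted p under 0.05 was reached by 945 genes at 2 h and 1149 at 4 h, where limma called 0 genes, and 1 without R72 4 h replicate 2. Among genes of the lists at 4 h, the responses differed for Ier3 by 1.15 ± 0.25 (adjusted p = 0.498), the dendritic cell and NF-kB gene Cd83 by 1.06 ± 0.29 (adjusted p = 0.646) and Tnfaip2 by 0.94 ± 0.28 (adjusted p = 0.698). Casp4 was at 1.00 ± 0.33 at 2 h (adjusted p = 0.932) and 0.95 ± 0.33 at 4 h (adjusted p = 0.778), Cdkn1a at 0.88 ± 0.34 (adjusted p = 0.932) and 0.80 ± 0.34 (adjusted p = 0.844), and Tnf at 0.34 ± 0.26 at 4 h. At 4 h 75.7% of the genes called in both genotypes had the larger change in P72, and at 2 h 50.9%.

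NF-kB target genes as a list responded more in P72 than in R72 with the preset correlation. At 4 h the difference was 0.36, and 0.35 relative to all genes (adjusted p = 1.32e-10, and adjusted p = 0.136 with an estimated correlation), with 0 of 46 members called over all genes and 2 adjusted over the list alone. At 2 h it was 0.21 and 0.16 (adjusted p = 0.000371, and adjusted p = 0.52 with an estimated correlation). The list's mean level rose from -0.67 ± 0.17 at 0 h to -0.05 ± 0.08 at 2 h and 0.93 ± 0.18 at 4 h in P72 (SD, n = 4), and from -0.49 ± 0.13 to -0.14 ± 0.11 and 0.67 ± 0.05 in R72. Within single slides the change at 4 h relative to all genes was 0.74 and 1.08 in P72 and 0.85 and 0.59 in R72. At 4 h 39 of the 46 genes had the higher change in P72. Markers of other cell types moved with them: at 4 h relative to all genes neutrophil markers differed by 0.94 (adjusted p = 2.16e-11), epithelial markers by 0.73 (adjusted p = 2.44e-06), dendritic cell markers by 0.44 (adjusted p = 7.49e-05) and macrophage markers by 0.43 (adjusted p = 1.25e-06), each with adjusted p = 0.171 with an estimated correlation. Of 49 such marker genes of blood cells, 48 had the higher change in P72. Abundant ones were at 0.92 ± 0.38 for S100a8, 0.79 ± 0.38 for S100a9 and 0.52 ± 0.28 for Lyz2. The neutrophil list reached -0.32 ± 0.35 in P72 and -0.30 ± 0.39 in R72 at 4 h (SD, n = 4), from -1.91 ± 0.35 and -0.90 ± 0.13 at 0 h, so the genotypes stood closer at 4 h than at 0 h.

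**Figure D5:**
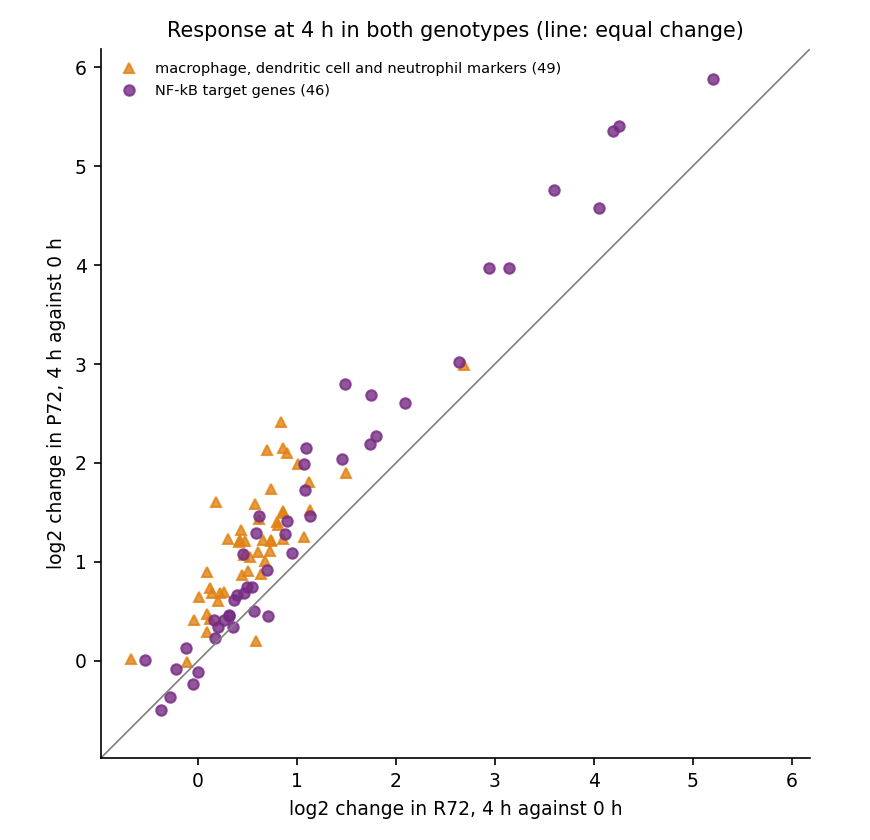
Log2 change from 0 h to 4 h in P72 (y axis) against R72 (x axis) for 46 NF-kB target genes and 49 markers of macrophages, dendritic cells and neutrophils, with the line of equal change. Above the line lie 39 NF-kB genes and 48 markers.

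Other lists differed at 4 h too, relative to all genes. Inflammasome genes differed by 0.40 (adjusted p = 0.00239) and sensing genes by 0.31 (adjusted p = 1.68e-05). Mitotic genes differed by -0.23 (adjusted p = 5.07e-08). With an estimated correlation these had adjusted p = 0.171, 0.109 and 0.257. At 2 h epithelial markers differed by 0.94 (adjusted p = 3.3e-07) and dendritic cell markers by 0.46 (adjusted p = 0.00124). Their adjusted p with an estimated correlation was 0.446 and 0.52. Macrophage and neutrophil markers differed by 0.27 and 0.37 at 2 h (adjusted p = 0.0186 for both, and adjusted p = 0.647 with an estimated correlation), but turned to -0.026 and -0.34 on the later scan dates alone. Apoptosis targets differed by -0.02 at 4 h (adjusted p = 0.454), against 0.115 on the later dates. The p53-dependent list differed by 0.16 at 2 h (camera p = 7.46e-06, p = 0.0284 with an estimated correlation) and 0.2 at 4 h (camera p = 7.31e-11, p = 0.00276 with an estimated correlation), with 0 of 100 members called at either time. Relative to all genes these were 0.113 and 0.189, against 0.097 and 0.172 with the slide as a fixed block. At 2 h that relative difference was 0.068 without R72 2 h replicate 2 and 0.024 on the later scan dates, where the call ended, and turned to -0.094 under normexp and -0.044 with the capped background. The limma and permutation p-values measure the spread between pooled samples, so differences between single mice were not assessed. Camera's p with the preset correlation sets the genes of a list against the other genes and does not measure that spread. Fisher's exact test below counts genes. In the p53+/+ and p53-/- fits the spread came from all groups.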

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

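The tests of neighbouring genes, of chromosome 11, of genes chosen at 2 h, of markers of other cell types at 0 h and 4 h, of the first scan date, of both parts of scaling, of the filter, of dim signal and of dim genes in p53-/- were chosen only after the results were seen, and the others before.

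Genes at least 2-fold apart between P72 and R72 over all times, 174 in number, were chosen on the mean of the 3 times. Their difference at 4 h was 0.955 times that at 0 h (95% interval over the genes 0.835 to 1.06), but this choice favours a constant difference and decides nothing. For 38 genes chosen on the 2 h arrays alone it was 1.11 times (0.742 to 1.34), with a median of 1.12 at 0 h. This argues against a difference in p53 activity after irradiation as their only cause, although the spread between arrays is left out. Of 127 such genes chosen on the 0 h and 4 h arrays, at least 96.9% kept their sign within each of the 2 slides that held both genotypes at 2 h. Medians were 1.15 and 1.70, against 1.41 at the other times, which argues against slide or scan date. Sex went with genotype within both slides and was not told apart there. Of the 167 with a coordinate, 71.3% had another within 5 Mb, against a median of 56.3% in 1000 random sets, of which the central 95% reached 64.1%, so strain variants in chromosome segments are a candidate explanation, as on chromosome 12 from 16726515 to 30015647, where 5 genes were all higher in R72. A segment around the Trp53 locus is not enough, since 8.38% lay on chromosome 11 (exact interval 4.66% to 13.7%), against 8.32% of all genes.

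NF-kB target genes rose more in P72 than in R72 at 4 h, by 0.36, a call lost with an estimated correlation (adjusted p = 0.136) and by fry (adjusted p = 0.051). Among 10000 lists matched on level and response, of median 0.141 and central 95% up to 0.245, theirs stood at percentile 100. Gene correlation was not matched, so a larger overall response stays open. At 4 h markers of neutrophils were at -0.05 in P72 against R72 (95% interval over the genes -0.12 to 0.07) and the NF-kB list at 0.20. This interval leaves out the spread between arrays, where the neutrophil list had an SD of 0.35 in P72 and 0.39 in R72. More transcripts of neutrophils at 4 h therefore stay open. At 0 h these markers were at -0.99 and the NF-kB list at -0.13, so fewer in untreated P72 samples may contribute. So may more transcripts of macrophages and dendritic cells at 4 h, whose markers outside the list were at 0.42 (95% interval over the genes 0.30 to 0.48). Scan date stays open: on the first date alone the difference, less that of all genes, was 0.134, on the later dates 0.559, with the date as a block 0.325 and with the slide as a block 0.281. A biological difference between the genotypes in the response of thymocytes or of the other cells was not told from these.

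At 4 h 63.4% and 64.2% of the called genes rose in P72 and R72, dim genes most, but with only probes well above background on every array 3465 rose and 4096 fell in P72 and 2685 and 3219 in R72. Of genes ranked by signal in 3 equal parts, the gap between the dim and the bright part was at least 1.01, which one shift of an array cannot make and which argues against scaling for the gap, while for the excess of rises scaling cannot be told apart, since centring on the median (at most 47.1% up) itself puts about as many genes above 0 as below. With a filter on 10 arrays outside the comparison, the untreated arrays of the other genotypes and all of p53-/-, at least 57.1% of calls were up and the gap was at least 0.70, which argues against a filter passed by 4 h arrays alone as the whole cause. Probes not well above background on those 10 arrays changed by 0.942 times as much as the dim part chosen there in P72 and by 0.542 times in R72, so a rise of all dim signal stays open in both. In p53-/- the dim part changed by 0.08 at 4 h, 0.075 times the 1.05 in p53+/+, but with 1 array each a handling step that needs no p53 cannot be told apart, and a change in the transcriptome of dying thymocytes was not tested.

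Over all 35 splits of the arrays no other gave as many genes in any comparison of 2 P72 or R72 groups. Chance gives that 1 time in 35 per comparison, unadjusted, and slides overlapped with genotype. The highest other splits called 8 genes for P72 at 2 h against 0 h (real 2966), 720 at 4 h (11621) and 1916 from 2 h to 4 h (6585). For R72 they called 409 (2675), 10 (9210) and 1406 (4298), the last being the split by scan date, beside which 5139 genes were called with the slide as a block, and 95.4% and 90.9% of genes called without a slide kept their direction within it. Between P72 and R72 they called 2 (186), 12 (263) and 1 (256) at the 3 times, and over all times 2 in 100 drawn splits (1961). For the difference of responses at 2 h 6 of 100 splits gave at least the 1 gene called, the highest 895, so chance cannot be excluded. What that split set apart was not tested. At 4 h 0 genes were called, all 100 splits gave as many, and the highest other gave 7.

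Some arrays stood apart from the other 3 of their group, by the share of the range taken by the gap to the nearest beyond Dixon's 95% critical value. This held for 12 of 246 sets of 4 arrays, and chance gives about 1 in 20. The R72 0 h replicate 4 array stood apart for neutrophil markers (0.935), R72 2 h replicate 4 for its 75th percentile (0.926, 1031.5 against 486.6 to 526.7), R72 2 h replicate 1 for glucocorticoid-responsive genes (0.869) and apoptosis targets (0.847), and R72 4 h replicate 4 for Fas (0.863). In P72 they were 0 h replicate 2 for heat shock (0.889), 0 h replicate 1 for immediate early genes (0.889), 2 h replicate 3 for metabolic p53 targets (0.866), 2 h replicate 1 for NF-kB targets (0.842), 4 h replicate 1 for the p53-dependent list (0.93) and heat shock (0.845), and 4 h replicate 2 for mitosis (0.877).

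Responses that differed by a test of the difference were also singled out, as list medians with camera's preset correlation. Between P72 and R72 none of the 10 calls of fixed lists at 2 h and 17 at 4 h held with an estimated correlation. At 2 h they included NF-kB targets at 0.21, macrophage markers at 0.32, dendritic cell markers at 0.50, neutrophil markers at 0.42 and epithelial markers at 0.98, and outside the fixed lists the p53-dependent list at 0.16 and the gene Thyn1 at 1.65 differed. At 4 h they included, beside NF-kB targets, inflammasome genes at 0.42, sensing genes at 0.33, mitotic genes at -0.21, macrophage markers at 0.44, dendritic cell markers at 0.46, neutrophil markers at 0.95, epithelial markers at 0.75, and outside the fixed lists the p53-dependent list at 0.2. Between p53+/+ and p53-/- 1089 genes differed, and 4 of 12 list calls held with an estimated correlation: apoptosis targets at 1.75, cell cycle and repair targets at 0.66, metabolic targets at 0.62 and heat shock genes at -0.73. Those of NF-kB targets at 0.29 and of the G1/S list at -0.75 were lost.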

How the results depend on the processing

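Median centring, the blocks for scan date and sex, the first or later dates alone and the capped background were chosen only after the data were seen, the others before. The causes of the changes below were not tested, except that fewer arrays, fewer genes or a stricter fold leave fewer calls by construction.

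Normexp, whose fit failed on 4 arrays with spots of very high local background, called 498, 5820 and 879 genes in P72 (2 h against 0 h, 4 h against 0 h, 4 h against 2 h, the order used throughout), 361, 1324 and 398 in R72, and 14, 38, 18 and 346 between P72 and R72 (0 h, 2 h, 4 h, all times). It called 1017 in p53+/+ after irradiation, 922 between irradiated and 15 between untreated p53+/+ and p53-/-, 22 in p53-/- and 228 for the difference of their responses. With the background capped 1495 and 4073 were called in P72 at 2 h and from 2 h to 4 h, 1409 and 7406 in R72, 78, 173, 112 and 1139 between P72 and R72, 8133 between irradiated and 71 between untreated p53+/+ and p53-/-. Under normexp G1/S turned in R72 at 2 h (0.222), and between P72 and R72 at 0 h interferon-stimulated genes (0.061), B-cell (-0.175) and single positive markers (0.064). The p53-dependent list turned between P72 and R72 at 0 h (0.061) and 2 h (-0.039, capped -0.039), and capped over all times (-0.003). Its difference of responses turned at 2 h (-0.094, capped -0.044). Of genes, 8030498J20Rik turned between P72 and R72 at 0 h (-0.076), Dctd in P72 at 4 h (0.184), Ier3 in R72 at 2 h (-0.282), Klf15 in R72 (0.644, capped 0.229) and Lrrc75a in P72 (0.198) from 2 h to 4 h. Capped, no other list or gene turned.

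With the authors' tabulated values 1847 genes were called in P72 at 2 h, 2812 in R72 from 2 h to 4 h, 496 between P72 and R72 at 4 h and 347 in p53-/-, and the p53-dependent list in P72 from 2 h to 4 h stood at 0.045. With quantile normalization 469 were called between P72 and R72 at 4 h and 131 in p53-/-, and that list stood at 0.059. A fold of at least 1.5 left 1822, 7662 and 4064 in P72, 1248 and 5804 in R72 at 2 h and 4 h, and 588 between the genotypes over all times. Probes well above background on every array left 7561 and 4080 in P72 and 5904 and 2439 in R72 (4 h against 0 h and against 2 h). With no filter 108, 173 and 159 were called between P72 and R72 at the 3 times, 124 in p53-/- and 627 for the difference of p53+/+ and p53-/- responses. It turned cell cycle targets (-0.089), glucocorticoid-responsive genes (-0.103) and interferon-stimulated genes (-0.008) in P72 at 4 h, NF-kB targets between irradiated p53+/+ and p53-/- (-0.123) and the p53-dependent list between P72 and R72 over all times (-0.005). All probes one by one gave 428 and 386 between P72 and R72 at 2 h and 4 h, and 3092 over all times.

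On the first scan date alone 564 genes were called in P72 at 2 h and 1479 from 2 h to 4 h, 354, 5610 and 58 in R72, and 12, 7, 4 and 361 between P72 and R72, and single positive markers at 0 h turned (0.048). The later dates gave 932 and 3359 in P72 (2 h against 0 h, 4 h against 2 h), 1154, 6042 and 2727 in R72, and 55 and 98 between P72 and R72 at 0 h and 4 h. On these dates neutrophil markers turned in P72 at 2 h (-0.095) and in the difference of responses at 2 h (-0.34), as did macrophage markers there (-0.026), apoptosis targets in that at 4 h (0.115), and mitotic genes between P72 and R72 at 4 h (0.014) and in R72 from 2 h to 4 h (-0.176). A block for scan date gave 143 at 4 h and 908 over all times. With the slide as a fixed block 17, 98, 14 and 130 were called between P72 and R72, 1352 between irradiated p53+/+ and p53-/- and 469 for the difference of their responses, and B-cell markers in the difference of responses at 4 h turned (-0.271). As a random block the slide gave 1049 over all times, 336 between untreated p53+/+ and p53-/- and 353 in p53-/-. Fitted on the 8 p53+/+ and p53-/- arrays alone, 0 genes were called in p53-/-.

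The replicate block gave 286, 533 and 466 between P72 and R72 at the 3 times. Same-numbered arrays correlated by -0.273 to 0.534 in their deviations, on average 0.134 against -0.045 for others, and 21 of 24 arrays were closest to one of their own number. These are hints from the data, and no label states that a number pairs arrays.

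The single gene with a different response at 2 h, Thyn1, was lost (0 genes) under normexp, no filter, the first and the later dates, median centring and the block for sex, and the block for sex called 1 gene at 4 h. NF-kB targets differed at 2 h by 0.165 relative to all genes with adjusted p = 0.52 with an estimated correlation and adjusted p = 0.22 by fry, and by 0.153 on the later dates (adjusted p = 0.163), 0.016 under normexp (adjusted p = 0.312) and 0.078 with the background capped (adjusted p = 0.0523). At 4 h they differed by 0.346 with adjusted p = 0.136 with an estimated correlation and adjusted p = 0.051 by fry, and by 0.134 on the first date (adjusted p = 0.119). The p53-dependent list differed at 2 h by 0.024 on the later dates, where it was no longer called.

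Leaving out each array in turn gave 1989 to 2829, 10591 to 11262 and 4625 to 6706 genes in P72, 1626 to 3080, 7953 to 8984 and 2207 to 5017 in R72, and 78 to 266, 112 to 465, 106 to 213 and 1488 to 2193 between P72 and R72. It gave 1219 to 5969 in p53+/+, 694 to 5792 between irradiated and 29 to 45 between untreated p53+/+ and p53-/-, 23 to 209 in p53-/-, 305 to 2281 for the difference of their responses, and 0 to 1 for those of P72 and R72. NF-kB targets differed by 0.112 to 0.221 at 2 h, where adjusted p = 0.0531 without R72 2 h replicate 2 (0.133), and by 0.236 to 0.395 at 4 h. The p53-dependent list, relative to all genes, stood at 1.66 to 1.737 and 1.803 to 1.88 in P72 at 2 h and 4 h (with all arrays 1.681 and 1.848), at 1.537 to 1.614 and 1.47 to 1.575 in R72 (1.56 and 1.527), and at 0.068 to 0.132 and 0.151 to 0.224 for the differences (0.113 and 0.189). The G1/S list in p53+/+ ranged from -0.766 to 0.048 and NF-kB targets between irradiated genotypes from -0.058 to 0.411, turning without the p53+/+ 4 h array. NF-kB targets in p53-/- ranged from -0.157 to 0.093, turning without the p53-/- 2 h array.

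Of the named genes 466 results kept direction and call with quantile normalization and 9 lost the call, and under normexp 392 did and 78 lost it. Of the list results 57 kept their direction and side of the threshold with an estimated correlation, called or not, and 90 lost the call.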

Other observations

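The genes and arrays in the next paragraph were chosen after their values were seen, as was the test of chromosome 11.

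The p53+/+ array at 2 h stood apart from the other p53+/+ arrays for genes that differed between P72 and R72. Rab6b was at -4.75 there and at 2.34 to 2.95 on the others, Prdm16 at -2.26 against -0.85 to -0.43 and Zfp933 at -0.36 against 0.63 to 0.77. Slc15a2 was at -6.45 and -6.02 on the untreated and 2.06 and 2.02 on the irradiated p53-/- arrays. In p53+/+ it was at -3.28 and -2.89 untreated, -2.68 at 2 h and 1.87 at 4 h. Asns was at 0.41 on the p53-/- 2 h array. H2-T3 lay between -7.30 and -4.68 on all P72 arrays and was also low on 2 R72 arrays, at -5.07 (2 h replicate 2) and -4.76 (4 h replicate 1). Vpreb3 was at -0.98 to 0.64 in p53-/- and -4.72 to -3.92 in p53+/+. Of 142 genes with a coordinate that differed between untreated p53+/+ and p53-/-, 34 lay on chromosome 11 (23.9%, odds ratio 3.52, two-sided Fisher's exact p = 1.32e-08).

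Lists not called at 4 h against 0 h in P72 or R72 stood as follows, relative to all genes. The unfolded protein response was at 0.05 and 0.00 (adjusted p = 0.715 and 0.819), clock genes at 0.34 and 0.00 (0.203 and 0.247), B-cell markers at -0.23 and -0.20 (0.248 and 0.315), erythroid markers at 0.33 and -0.03 (0.484 and 0.952), fibroblast and endothelial markers at 0.48 and 0.12 (0.136 and 0.642), adipocyte markers at 0.87 and 0.72 (0.236 and 0.559) and double negative markers at 0.44 and 0.20 (0.0652 and 0.484). Sex-linked genes were at 0.62 in P72, with a test in the other direction (adjusted p = 0.767).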
